A study of Mus musculus with 8 samples.

How the data were processed

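Total RNA from 8 samples of whole cortex from mouse embryos of mixed strain background at embryonic day 15.5 was amplified, labelled with Cy3 and hybridised to whole mouse genome arrays of 4 per slide, per the labels' protocols. The labels put 4 samples in the control group and 4 in the mutant group. Scanner images were read with Agilent Feature Extraction 10.5, per the submitters' processing notes. Per the file headers, each deposited scanner file holds spot intensities of 1 colour. They include a processed signal, which is background-subtracted and detrended within the array, and the median brightness of spot and local background. The deposited series matrix holds values on a log2 scale. Set against the scanner files, its columns kept the rank order of the median spot intensity (Spearman 1 across probes on every array). Their sorted values differed by at most 0.0706 between arrays, as after quantile normalization, and their medians ran from 7.47 to 7.48. Scale, centring and direction of the matrix were thereby settled. Which tool the authors used for that normalization is not given in the sources used here, and 0 of its columns went unmapped.

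Of 45018 spots per array, 1639 control spots were left out, as were spots marked as outliers by the scanner software (58 to 432 per array). No spot was saturated (0 over all arrays). The main values were log2 of the processed signal minus the 75th percentile of each array, and spots of 1 probe were averaged. A probe was kept if well above background on at least 4 of 8 arrays, which 30651 of 41174 probes (74.4%) were. The files carry no gene symbols, so accessions were matched without version to the RefSeq table of the assembly GRCm38.p6. This gave a symbol to 24844 probes, or 17178 genes, and 16330 probes kept the accession. The array design was annotated on another assembly, so no coordinates are given and the table served only for names and neighbours. The probe with the highest mean over 8 arrays stood for a gene, leaving 14644 named genes and 8811 accessions. Of the called genes 81 had further measured probes. Of those 103 probes 101 had the same sign and 86 also an unadjusted p under 0.05, and the 2 of opposite sign did not reach it.

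Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, group as the only term) with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05. The 34 gene lists were tested with camera at a preset correlation of 0.01 where at least 5 members were measured, which 33 were, and adjusted over lists. Adjustment over the list alone treats the members of 1 list as the only genes tested. The Pbx1 probes and list means also had exact two-sided permutation tests. No fold is given for a probe not well above background on any array of a group. The lists, tests, alternatives and the rule for named genes were fixed before the data were examined, except the input of normexp and those said below to have been chosen afterwards. Named were the measured genes of the TALE list and the 12 largest increases and 12 largest decreases among called genes with non-overlapping groups. Named as well were up to 4 members per list with the smallest p among those past the threshold over all genes or over the list, or else the 2 with the smallest p. Where fewer than 10 genes passed in a direction the list was to be filled to 10, which was not needed. Clone, RIKEN, Gm and LOC names and accessions were counted and not named.

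On simulated data with the means and spreads of this comparison for 23089 genes, 200 of them changed, 20 draws gave 2621 calls, of which 5.19% were unchanged genes. The recovered share was 40.1% at a log2 change of 0.5, 64.3% at 1 and 82.0% at 2. A list moved by 0.5 was called, and no other list was. Genes were drawn independently and without a slide effect, so the draws do not show false calls among genes that vary together. The move of 0.5 was also larger than the mean shift of any list called below, the largest being -0.28.

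Slides were scanned in 2 sessions on 1 day, so scan and slide coincide. The first principal component (51.9% of the variance) parted the slides. Deviations from the group means of the same-numbered control and mutant correlated at 0.29 to 0.53 over genes, above 0.1 for all 4 pairs. Control and mutant arrays of other numbers on the same slide correlated at 0.36 to 0.55 and arrays of different slides at -0.76 to -0.32. With the mean of each group on each slide removed, the same-number correlation was -0.002 on slide 1 and -0.10 on slide 2. The correlation of same-numbered arrays was thus like that of other arrays on a slide, and the numbers gave no sign of pairing beyond it. With 2 arrays of a group per slide, each value rests on 1 contrast, so pairing is not excluded. Within a group, arrays correlated at 0.983 to 0.994 over genes with an SD of differences of 0.35 to 0.68, so none was a copy of another. The labels name no litters and do not say whether cortices were pooled. Xist was well above background on 1 control and 1 mutant array, so arrays with this female-expressed transcript were balanced between groups. These were control 1 and mutant 1, both on slide 1, so the Xist covariate is partly tied to the slide. The Y-linked Ddx3y, Eif2s3y and Uty were well above background on all other arrays and not on these. No array thus showed Xist with these transcripts, but single embryos cannot be told from pools of 1 sex.

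Alternatives were normexp background correction (offset 50), quantile normalization, both together, median scaling, the deposited log2 matrix, a replicate block, a slide block, each slide alone, each array left out, no filter on dim probes and a filter over all 8 arrays. Further ones were the mean over probes, a trended robust prior, array weights, an Xist covariate, thresholds of 0.1 or 1.5-fold, every probe, an estimated correlation, and fry. The files hold the median and not the mean spot intensity, so normexp used the median. Plots were drawn with matplotlib 3.10.9 in Python 3.11.15.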

Results

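Transcript levels were measured in whole cortex dissected from mouse embryos at embryonic day 15.5. The series compared 4 control samples, which carried a floxed and a wild-type allele of Pbx1, with 4 mutant samples, which carried a floxed and a null allele together with Emx1-cre. Emx1-cre expresses Cre recombinase in the Emx1 lineage, which includes the progenitors and excitatory neurons of the dorsal cortex. Pbx1 encodes a homeodomain transcription factor of the TALE family, and the comparison asks which transcripts differ in cortex when it is removed from that lineage. The mutants differed from the controls in the Cre and in the null allele as well as in the deletion, so these cannot be told apart here. Each sample was read on 1 single-colour array of 45018 spots, and the labels do not say whether a sample is a single embryo or a pool. Between 69.3% and 79.8% of spots per array were well above background, and the median processed signal ran from 107 to 180 units. The 8 arrays lay on 2 slides, each with 2 control and 2 mutant arrays. Values below are log2 signals relative to the 75th percentile of each array, differences are mutant minus control with the limma standard error, and the precision is limited by the 4 arrays per group.

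Pbx1 itself was lower in every mutant array. The brightest of its 3 probes fell from 2.95 ± 0.04 (SD, n = 4) in controls to 1.31 ± 0.05 (SD, n = 4) in mutants, a difference of -1.63 ± 0.05 or 3.10-fold, with a limma adjusted p of 4.55e-05 over all genes. The other probes were 3.73-fold and 4.17-fold lower, each with an adjusted p of 0.000201 when every probe was tested. All 3 probes gave an exact two-sided permutation p of 0.0286, the smallest that 70 assignments of 8 arrays can give. The difference was -1.59 on slide 1 and -1.68 on slide 2. A signal of 24.0% to 32.3% of the control level was left. The files do not place the probes relative to the floxed region, so the size of the fall does not measure how complete the deletion was.

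In the TALE list, of which 12 genes including the Pbx-interacting Pbxip1 were measured, Pknox1 changed in the opposite direction to Pbx1. Pknox1, also called Prep1, encodes a DNA-binding partner of Pbx proteins, and its signal rose 3.06-fold, from 0.61 ± 0.09 (SD, n = 4) to 2.23 ± 0.08 (SD, n = 4), with a limma adjusted p of 0.000274. This gene had 1 probe. No other TALE gene passed over all genes tested. Adjusted over the list alone, 3 genes were higher (Pknox1, Pknox2 and Meis2) and 2 lower (Pbx1 and Pbx3). The differences were 0.31 ± 0.06 for Pknox2, 0.35 ± 0.09 for Meis2 and -0.58 ± 0.18 for Pbx3. The values for Pbx2, Pbx4, Meis1, Meis3, Tgif1, Tgif2 and Pbxip1 lay between -0.12 and 0.20 and did not pass. The family as a whole was not called by the set test (camera adjusted p = 0.794).

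**Figure D1:**
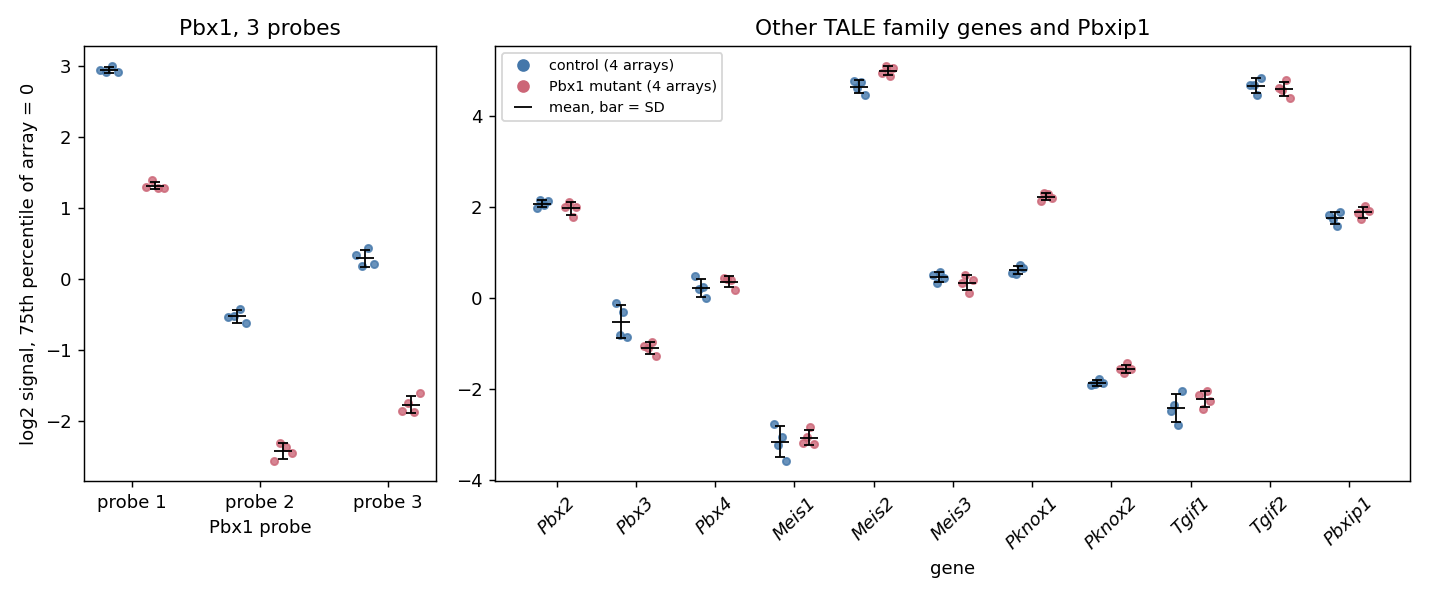
Log2 signal of the 3 Pbx1 probes (left) and of the other measured genes of the TALE list, Pbxip1 included (right), relative to the 75th percentile of each array; each dot is 1 array, and black marks are the group mean with its SD over 4 arrays. All mutant dots lie below all control dots for each Pbx1 probe, and all mutant dots lie above all control dots for Pknox1.

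Over the whole array, 275 of 23455 genes or accessions differed between mutant and control cortex, 182 higher and 93 lower in the mutants. Of these, 219 had a gene symbol and 56 were known by accession only. The median fold was 1.58 among the higher genes and 1.62 among the lower ones, and 36 and 16 genes passed 2-fold in each direction. Over all genes tested, mutant and control values did not overlap for 9.72%, where chance gives 2.86% on average over relabellings. Genes vary together across arrays, so a single relabelling can lie far from that average. By limma, 3039 genes had an unadjusted p under 0.05. Another split of the arrays into 4 and 4 gave 2920, and the split by slide gave 5371.

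In the values used here the largest increase was that of Dbx1, a homeobox gene of ventricular zone progenitor domains, at 7.71-fold (2.95 ± 0.25, adjusted p = 0.00713). Klhdc8a rose 4.38-fold. Over the alternatives the smallest log2 size was 1.74 for Dbx1 and 2.01 for Klhdc8a, so the order of these genes depends on the processing. Ltbp2, which encodes a latent TGF-beta binding protein, rose 3.85-fold, and Gpd1, the cytosolic glycerol-3-phosphate dehydrogenase, rose 3.58-fold. The remaining increases among the 12 largest ran from 2.69-fold to 3.38-fold. They comprised the chitinase-like gene Chil3, the G protein subunit Gna14, the natriuretic peptide clearance receptor Npr3, Pknox1, Fam163a, the DM-domain gene Dmrta1, Tecta and Angptl1. For Tecta and Angptl1, whose probes were dim, the size shrank to 0.50 and 0.39 on the log2 scale under normexp with quantile normalization, and Angptl1 passed in 6 of 25 alternatives. Among the genes that were lower was Nr0b1 (Dax1), an orphan nuclear receptor, which was well above background on all 4 control arrays and not well above background on any of the 4 mutant arrays. It passed (adjusted p = 0.00845) but not after normexp, and no size is given for it, as the mutant signal was not above background. Smoc1, a secreted calcium-binding matrix protein, was 3.96-fold lower (-1.98 ± 0.08, adjusted p = 0.000274). Apobec1, the cytidine deaminase that edits apolipoprotein B messenger RNA, was 3.15-fold lower by its brighter probe, whereas its other probe differed by -0.01 and did not pass even without adjustment. The homeobox genes Msx3 and Nkx2-3, the BMP receptor Bmpr1b, the retinol-binding protein Rbp1, the transmembrane protein Flrt3, the guanylate cyclase subunit Gucy1b2, Rai14 and Ccbe1 were 2.25-fold to 2.62-fold lower. Of the other Ccbe1 probes, one differed by -1.82 and the other by -0.57, the latter not passing even without adjustment. After normexp Msx3 and Bmpr1b shrank to -0.35 and -0.47 and did not pass, and with the mean over probes Apobec1 was at -0.83 and did not pass. Over the alternatives the Nkx2-3 difference shrank to as little as -0.59. Nkx2-3, Rbp1 and Ccbe1 each passed in 8 of 26 alternatives.

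**Figure D2:**
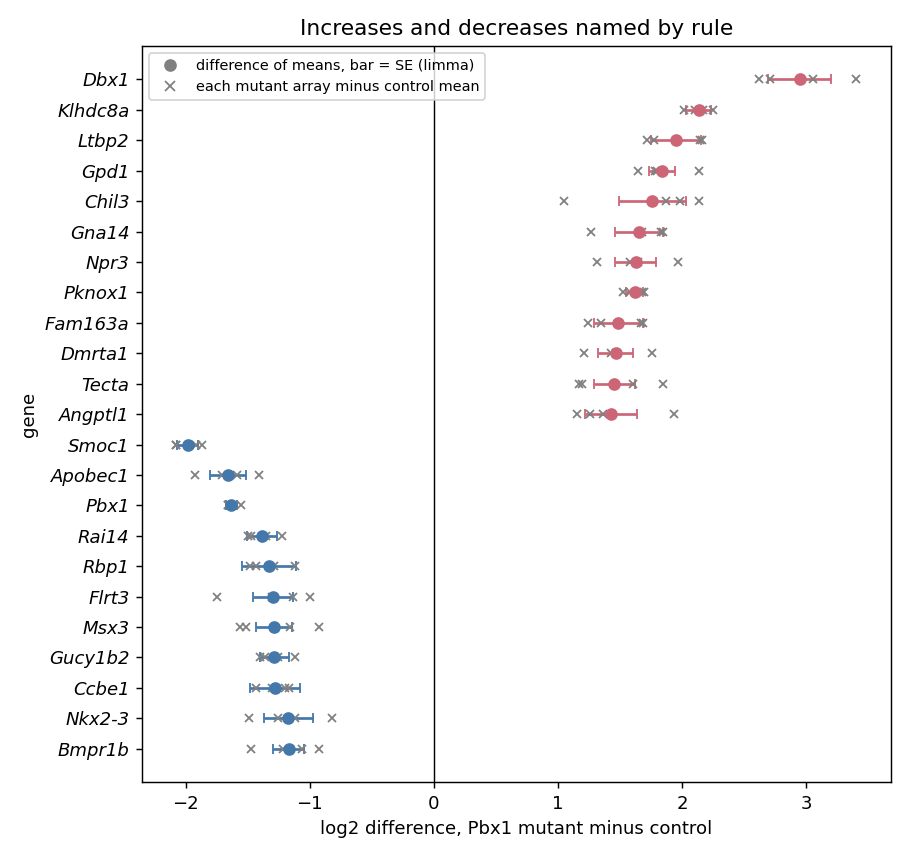
Log2 difference, mutant minus control, of the 12 genes with the largest increase and the 12 with the largest decrease among called genes with non-overlapping groups; circles are differences of means with the limma SE as bars, and crosses are the 4 mutant arrays minus the control mean. Nr0b1, which the same rule names, is left out, as its probe was not well above background in mutants.

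The number of genes that passed depended on the fit. With the replicate block, which leaves fewer degrees of freedom, 3 genes passed (Pbx1, Smoc1 and Pknox1), and with the slide as a block 266 passed, of which 217 were among the 275. On 2 against 2 arrays, limma called 1 gene on slide 1 and 0 on slide 2, where 2148 had an unadjusted p under 0.05. The count fell to 71, 168, 116 and 157 without control 1, 2, 3 and 4 in turn, and to 72, 158 and 78 without mutant 1, 2 and 4. It was 25 after normexp background correction and 24 after median scaling, where 11 were higher and 13 lower.

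Genes of upper layer neurons that passed were mostly lower, and those of deep layer neurons were higher. A difference between the lists was not tested. Of 21 measured upper layer genes, 4 fell and 1 rose over all genes tested, and 10 fell and 4 rose adjusted over the list alone. Cux2 and Cux1, homeobox genes of upper layer neurons, were 1.94-fold and 1.47-fold lower (-0.96 ± 0.15, adjusted p = 0.0391; -0.56 ± 0.09, adjusted p = 0.0353). The receptor phosphatase Ptprk was 1.58-fold lower, with 1 of its other probes at -0.38 and not passing without adjustment, and the semaphorin receptor Plxnd1 was 1.51-fold higher. Cux2 passed in 8 of 26 alternatives, Cux1 in 9, Ptprk in 19 and Plxnd1 in 9. The upper layer list was lower by camera (median -0.16, adjusted p = 0.0233). That call was lost with an estimated correlation (adjusted p = 0.667), with the replicate block (adjusted p = 0.0842) and with the slide as a block (adjusted p = 0.0601). It was lost as well with quantile normalization (adjusted p = 0.157), and over all alternatives the adjusted p ran from 0.00262 to 0.667. The list passed fry (adjusted p = 0.0204). The mean shift of the list was -0.20 on slide 1 and -0.36 on slide 2. Without control 3, control 4, mutant 1 or mutant 3 the list did not pass (adjusted p = 0.117, 0.0508, 0.0768 and 0.0515). Of 19 deep layer genes, 3 rose and 0 fell (12 had an unadjusted limma p under 0.05). They were Zfpm2, a GATA cofactor, at 2.12-fold, Lmo3 at 1.91-fold and Crym, which encodes a thyroid hormone binding protein, at 2.32-fold. Zfpm2 passed in 20 of 26 alternatives, Lmo3 in 21 and Crym in 7. In all, 7 deep layer genes were higher and 3 lower adjusted over the list alone, among them Foxp2 at -0.76 ± 0.16. The deep layer list did not pass camera (adjusted p = 0.224) but passed fry (adjusted p = 0.0204), with a range of 0.0204 to 0.667 over all alternatives.

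Subplate genes were higher in the mutants by camera at the preset correlation, but not with an estimated correlation (adjusted p = 0.283). Of 16 measured, 4 rose and 1 fell over all genes, and 7 rose and 1 fell adjusted over the list alone. The nuclear receptor Nr4a2, a marker of subplate neurons, rose 1.64-fold, the potassium channel subunit Kcnab1 1.58-fold (its other probe, at 1.05, did not pass without adjustment) and Tmem163 1.46-fold, whereas the microsomal glutathione transferase Mgst1 was 1.48-fold lower. Nr4a2 passed in 14 of 26 alternatives, Kcnab1 in 7, Tmem163 in 15 and Mgst1 in 9. The list was higher by camera (median 0.28, adjusted p = 0.00378), and not with the replicate block (adjusted p = 0.0825). Its mean shift was 0.19 on slide 1, 0.22 on slide 2 and 0.20 with the slide as a block (adjusted p = 0.0227). Without mutant 3 the adjusted p was 0.0518, and over all alternatives it ran from 0.000142 to 0.283. The list passed fry (adjusted p = 0.000516). Among 17 Cajal-Retzius and marginal zone genes, the calcium-binding protein Calb2 rose 1.77-fold. Calb2 passed in 8 of 26 alternatives. Of these 17, 3 were higher and 1 lower adjusted over the list alone. Reln was 0.49 ± 0.14 higher and did not pass (adjusted p = 0.196), nor did the list (camera adjusted p = 0.0531). It passed without control 4 (adjusted p = 0.00529) and without mutant 2 (adjusted p = 0.00312), the lowest of a range that reached 0.667. No gene of the 18 in the reelin pathway list passed limma over all genes or over the list alone, and 2 had an unadjusted p under 0.05. Its smallest p-values were those of Reln and Map1b.

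Of 28 neuronal maturation genes, Nrxn1, a presynaptic adhesion protein, rose 1.44-fold (0.53 ± 0.09, adjusted p = 0.0484). Nrxn1 passed in 7 of 26 alternatives. There were 3 higher and 0 lower adjusted over the list alone, the others being Camk2b and Cntn1. In all, 21 of the 28 had a positive difference, and the list was higher by camera (median 0.09, adjusted p = 0.00378). The call was lost with an estimated correlation (adjusted p = 0.667), with the replicate block (adjusted p = 0.0551) and without control 4 (adjusted p = 0.0508). It was also lost with normexp (adjusted p = 0.184) and with median scaling (adjusted p = 0.196), within a range of 6.47e-06 to 0.667, and it did not pass fry (adjusted p = 0.166). The mean shift was 0.13 on slide 1, 0.12 on slide 2 and 0.13 with the slide as a block (adjusted p = 0.0205).

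Cell cycle genes were lower as a list by camera at the preset correlation, but not with an estimated correlation of 0.644 (adjusted p = 0.667). None of the 34 measured members passed limma alone, over all genes or over the list, and 14 had an unadjusted p under 0.05. However, 33 of the 34 had a negative difference (median -0.17, camera adjusted p = 1.05e-09). The exact permutation p of the list mean was 0.0571. It did not pass fry (adjusted p = 0.189), and over all alternatives the adjusted p ran from 2.03e-14 to 0.667. The smallest p-values belonged to the thymidylate synthase gene Tyms at -0.31 ± 0.08 and the mitotic cyclin gene Ccnb1 at -0.28 ± 0.08. The mean shift of the list was -0.22 on slide 1, -0.09 on slide 2 and -0.15 with the slide as a block (adjusted p = 1.2e-08). Radial glia genes showed no common direction (23 measured, camera adjusted p = 0.947). The endothelin receptor Ednrb was 1.54-fold lower and the glutamate transporter Slc1a3 was 1.42-fold higher, and 6 were higher and 4 lower adjusted over the list alone. These included Aldoc at -0.52 ± 0.09 and Ptprz1 at 0.27 ± 0.05. The Ptprz1 value rests on 3 mutant arrays and turned to -0.47 with the mean over probes. Ednrb passed in 19 of 26 alternatives and Slc1a3 in 11. Of 17 intermediate progenitor genes, Hes6 was 1.22-fold lower. Hes6 passed in 5 of 26 alternatives. Adjusted over the list alone 2 were higher and 3 lower, with Neurod1 at 0.64 ± 0.15, Slc17a6 at 0.23 ± 0.06 and Tmem158 at -0.24 ± 0.06 (list camera adjusted p = 0.206). Without control 3 the list passed (adjusted p = 0.0493).

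**Figure D3:**
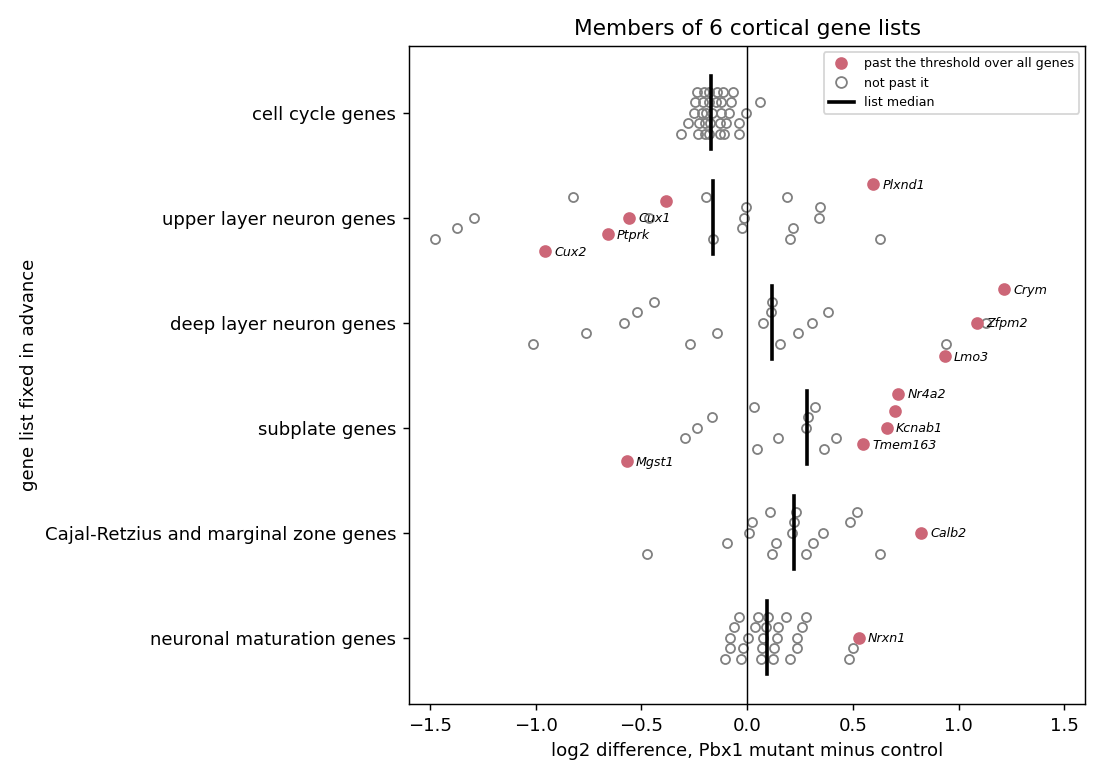
Log2 difference, mutant minus control, of each measured member of 6 gene lists; filled dots passed limma over all genes, open dots did not, and black bars are list medians. Of the 34 cell cycle dots 33 lie left of 0, and the upper layer median is -0.16 against 0.28 for the subplate list.

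Areal identity genes changed singly. Of 19 caudal cortex genes, 4 rose and 1 fell, and 5 rose and 3 fell adjusted over the list alone. Emx1, the homeobox gene whose name the Cre line carries, was 1.54-fold lower (-0.62 ± 0.06, adjusted p = 0.00819). Dmrta1 rose 2.76-fold, Lix1 1.46-fold and the ephrin Efna5 1.39-fold, and the remaining riser was Crym, which the deep layer list also holds. Emx1 and Dmrta1 each passed in 19 of 26 alternatives, Lix1 in 8 and Efna5 in 9. The other Efna5 probe differed by 0.11 and did not pass without adjustment. Of 17 rostral genes, Lmo3, which the deep layer list also holds, rose over all genes. Adjusted over the list alone 2 were higher and 2 lower, with Lmo4 at 0.63 ± 0.12, Cdh8 at -0.33 ± 0.09 and Etv1 at -0.58 ± 0.17. Camera called neither list (adjusted p = 0.44 for caudal and 0.526 for rostral genes). No Hox gene passed limma among 8 measured and 0 had an unadjusted p under 0.05. Hoxd3 and Hoxc5 were well above background on 4 and 6 of the 8 arrays, at 0.47 ± 0.34 and -0.26 ± 0.29.

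In the Wnt and cortical hem list of 31, the Frizzled receptors Fzd8 and Fzd5 were 1.67-fold and 1.46-fold lower. After normexp Fzd5 was at -0.07 and did not pass. Adjusted over the list alone 2 were higher, Wnt5a at 0.81 ± 0.14 and Id3 at 0.72 ± 0.13. The Wnt5a difference shrank to as little as 0.26 over the alternatives, and the lowest for Id3 was 0.61. Among 18 retinoic acid genes, Rbp1 and the retinaldehyde reductase gene Dhrs3 were 2.51-fold and 1.74-fold lower. These were also the 2 calls over the list alone. Dhrs3 passed in 6 of 26 alternatives. In the FGF list of 23, Flrt3 was 2.46-fold lower, and adjusted over the list alone 2 were higher and 3 lower. The receptors Fgfr2 and Fgfr1 were at -0.45 ± 0.09 and 0.45 ± 0.09, and Fgf9 at 0.30 ± 0.09. Hes6 was the only call among 20 Notch genes, over all genes and over the list alone. The Notch list passed camera without control 3 (adjusted p = 0.0493). Pmaip1, a proapoptotic p53 target, was 1.71-fold lower among 20 p53 and apoptosis genes, and Perp at 0.44 ± 0.09 passed over the list alone. The Pmaip1 difference shrank to as little as -0.39 over the alternatives, and the gene passed in 19 of 26. None of 21 immediate early and stress genes passed limma over all genes or the list alone, and 3 had an unadjusted p under 0.05. Among them were Hspa1a at -0.21 ± 0.05 and Ier2 at 0.35 ± 0.10. Over the alternatives the Hspa1a difference ran from -0.31 to 0.19, so its direction turned, whereas Ier2 stayed higher. In the values used here none of these 6 lists passed camera, with adjusted p from 0.206 to 0.947. Among all lists, the signs of the median, the mean and the camera direction differed for the reelin, cadherin, FGF, Wnt, retinoic acid, p53, red blood cell, endothelial and control lists, none of which passed.

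Guidance and adhesion genes changed in both directions. Of 37 semaphorin, plexin, netrin and slit genes, 2 rose and 3 fell, and 5 rose and 6 fell adjusted over the list alone. Sema6d was 1.46-fold lower and the plexin Plxna4 was 1.75-fold lower (-0.81 ± 0.10, adjusted p = 0.0165), whereas Plxnd1 and Sema4f were 1.51-fold and 1.26-fold higher. Sema6d passed in 19 of 26 alternatives, Plxna4 in 16 and Sema4f in 6. Of 16 Eph and ephrin genes, Epha8 rose 1.61-fold and Efna5 1.39-fold. The Epha8 probe was dim, its difference shrank to 0.12 under normexp with quantile normalization, and it passed in 11 of 26 alternatives. In that list 2 were higher and 2 lower adjusted over the list alone, the latter being Epha3 at -0.50 ± 0.09 and Ephb3 at -0.40 ± 0.12. Camera did not call that list (adjusted p = 0.347), whereas fry did (adjusted p = 0.0204), and over all alternatives the adjusted p ran from 0.0204 to 0.916. Of 23 cadherin genes, the protocadherin Pcdh20 rose 1.93-fold. In total 3 were higher and 3 lower adjusted over the list alone, with Pcdh8 at 0.26 ± 0.06, Pcdh18 at -0.33 ± 0.07 and Cdh20 at -0.40 ± 0.09. Camera called neither the cadherin list (adjusted p = 0.912) nor the semaphorin list (adjusted p = 0.347).

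In the lists of markers of other cell types and regions, Cxcl12, Calb2 and Grik4 passed over all genes. Whether this share differs from that over all genes (275 of 23455) was not tested. Camera called none of these lists in the values used here. The GABAergic interneuron list was lower by camera in 3 of 28 alternatives, with a lowest adjusted p of 0.0179. No gene passed limma over all genes in the lists for GABAergic interneurons (20 measured, 1 with an unadjusted p under 0.05), striatum and ventral forebrain (18, 3), choroid plexus (12, 0), red blood cells (8, 1), endothelium (18, 0), microglia and macrophages (15, 2) or oligodendrocyte precursors and astroglia (16, 5). Over the list alone Klf1, an erythroid transcription factor, was higher (0.59 ± 0.13) and the chemokine Pf4 was lower (-0.57 ± 0.11), though it turned to 0.13 after normexp. Values that did not pass included Npy at -1.05 ± 0.30, Gad2 at -0.34 ± 0.15, Zfp521 at 0.53 ± 0.13, Rxrg at -0.89 ± 0.30, Emcn at -0.17 ± 0.08, Esam at 0.14 ± 0.09, Nfix at 0.24 ± 0.07 and Sox8 at -0.28 ± 0.08. In the pericyte and meningeal list of 20, the chemokine Cxcl12 was 1.97-fold lower. Over that list alone 3 were higher and 2 lower, with Rgs5 at 0.57 ± 0.11, Pdgfrb at 0.35 ± 0.07 and Fn1 at -0.49 ± 0.13. Calb2 was the only call over all genes of 10 thalamic and diencephalic genes, with Tcf7l2 at 0.43 ± 0.08 passing over the list alone. The kainate receptor Grik4 was the call of 12 hippocampal genes, at 1.87-fold higher. Grik4 passed in 11 of 26 alternatives. Choroid plexus genes were high on 1 array, mutant 3, where the list mean was -1.32 against -3.44 to -3.17 on the other mutant arrays. The transthyretin gene Ttr, the most abundant choroid plexus transcript, differed by 2.95 ± 1.96 between groups, and Kcne2 by 1.92 ± 1.31, and neither passed. None of 13 control genes passed limma (1 had an unadjusted p under 0.05), with Hprt at -0.15 ± 0.05 and Tbp at -0.10 ± 0.05. Of the sex-linked genes 4 were measured, too few for a set test, and Kdm5d and Eif2s3y differed by -0.10 ± 1.39 and 0.07 ± 3.05.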

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

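In each group of 4 arrays, the gap between the extreme array and its neighbour was set against the range of the group, and the ratio was compared with Dixon's 95% critical value for 4 samples. Of 305 such groups over named genes, list means and array measures, 18 passed it, and chance gives about 1 in 20, or 15.25. The choroid plexus test below was chosen after the values had been seen.

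Control 3 stood apart in 5 of these, with Emx1 low (ratio 0.856, 2.55 against 2.74 to 2.78), Ednrb low (0.832), Klf1 low (0.887), Kcnab1 high (0.888) and Plxna4 high (0.892, 3.08 against 2.65 to 2.70). Control 4 was high for Slc1a3 (0.933) and for the mean of radial glia genes (0.860). Mutant 4 was low for Pbx4 (0.844) and for the mean of intermediate progenitor genes (0.844), and high for Lmo3 (0.912) and Pf4 (0.856). Mutant 2 was high for Pbx1 (0.897, 1.39 against 1.29 to 1.30), far below the controls, and high for Zfpm2 (0.882) and low for Reln (0.890, 3.11 against 3.44 to 3.49). Mutant 1 was low for Cntn1 (0.830) and high for the mean of subplate genes (0.832).

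Choroid plexus genes were far higher on mutant 3 than on the other mutant arrays, both for the list mean (ratio 0.873) and for Kcne2 (0.873, 0.00 against -5.97 to -5.21). Of 12 measured members, 8 were highest on that array. Kcne2 lay 5.97, Clic6 3.40 and Aqp1 2.37 above the median of the other 7 arrays on the log2 scale. Folr1 and Prlr lay 0.36 and 1.07 below that median. Ttr was among the 8, but it was well above background on only 1 control and 3 mutant arrays, so no distance is given for it. Clic6, Aqp1, Folr1 and Prlr were named after their values were seen. A candidate explanation is choroid plexus tissue in that dissection. It leaves the lower Folr1 and Prlr values unexplained. A difference in that sample's embryos stays open and untested. Without mutant 3, 192 genes and 2 lists passed.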

How the results depend on the processing

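Alternatives named here as added (with both median scaling or normexp and a slide block, and without the Xist arrays) were chosen after seeing the data. The Pbx1 fall stayed past the threshold in 15 of 17 other settings (adjusted p from 1.93e-05 to 0.303). On slide 1 alone it was -1.59 (adjusted p = 0.173) and on slide 2 alone -1.68 (adjusted p = 0.303), where 2 against 2 arrays leave few degrees of freedom. None of the 54 called named genes reversed in any setting, which for the blocks and for subsets of the same arrays follows largely from the way the genes were selected.

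The 275 changed genes became 25 with normexp, 24 with median scaling, 3 with the replicate block, 1 on slide 1 and 0 on slide 2, 97 without a filter on dim probes, 544 with the trended robust prior, 426 with array weights and 138 with the Xist covariate. They became 676 at a threshold of 0.1 and 172 at 1.5-fold. Leaving out each array gave 71 to 192. Added settings gave 148 with median scaling and the slide block, 9 with normexp and the slide block, and 3 without the 2 Xist arrays. The looser and stricter thresholds shift the count by construction. Fewer arrays and the degrees of freedom that the replicate block takes lower the power, but their part in those shifts was not tested. Leaving out 1 array gave 71 genes without control 1 and 192 without mutant 3, so which array was left out mattered too. For median scaling, the rise from 24 to 148 when the slide entered the fit shows that part of the loss came from the slides. For normexp and the rest, the cause was not tested. Normexp moved the median difference of all genes to 0.16, against 0.02. With median scaling 45.8% of calls were higher, and with the slide block added 41.2%, against 66.2%. All 275 genes kept their direction under median scaling, and 269 did under normexp. Quantile normalization, normexp with quantile normalization and the deposited matrix called 223, 349 and 266 genes and shared 198, 217 and 198 with the 275. Of the 54 named calls, 14 held with normexp, 16 with median scaling, 44 with the slide block, 8 with normexp and the slide block, 3 without the Xist arrays, 26 without control 1, 41 without control 2, 31 without control 3, 37 without control 4, 27, 35, 37 and 28 without mutant 1, 2, 3 and 4, and 3 with the replicate block.

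The 4 called lists became 1 with the replicate block (the cell cycle list), 2 on slide 2 alone and 0 with an estimated correlation. Leaving out each array gave 2 to 5. The preset correlation understates the variation shared by members such as the cell cycle genes, whose estimate was 0.644. The estimate was 0.199 for neuronal maturation and 0.0323 for upper layer genes. For the subplate list it was -0.0338, below the preset, yet the adjusted p by camera with that estimate was 0.283. Shared variation thus does not account for the loss of the subplate call. A call can be lost with an estimated correlation even where that estimate lies below the preset. Such a loss is therefore not by itself a sign of shared variation among members. For the other lists, the part of shared variation in the loss was not tested. With fry 4 lists passed as well, but the cell cycle and neuronal maturation lists were not among them. Over 28 other settings, the cell cycle list was called in 26, subplate in 24, neuronal maturation in 18, upper layer in 14 and Cajal-Retzius in 11. Lists not called here were called in 4 (intermediate progenitor), 3 (deep layer, GABAergic), 2 (Notch) and 1 (rostral, Eph). Dim probes limit the rest. Nr0b1, not above background in mutants, passed in 20 of 25 other settings.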

Other observations

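The tests of neighbouring genes and of embryo stage below were chosen after the called genes had been seen; the splits, the matched random lists and the family scan were set before.

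Called genes were more frequent on chromosome 1, which carries Pbx1, than elsewhere. With Pbx1 itself left out, 25 of 827 tested genes on chromosome 1 passed (3.02%), against 1.40% on other chromosomes (Fisher's exact p = 0.000885, over genes, which are not independent). Of the 200 tested genes nearest to Pbx1, 10 passed, 8 higher and 2 lower, where 2.88 would match the rate elsewhere (Fisher's exact p = 0.00084). No window of that size on another chromosome held as many, the highest holding 8. Of the nearest 100 genes 5 passed, more than in 95.9% of windows of that size, but 337 windows on other chromosomes held as many. Of the nearest 381, 15 passed, which no window on another chromosome reached. The 10 among the nearest 200 were, named here after their values were seen, Cacna1e, Xpr1, Fam163a, Angptl1, Olfml2b, Usf1, Atp1a2 and Grem2 (higher) and Usp21 and Casq1 (lower). Neighbours were taken from gene order in the assembly GRCm38.p6. Variants of another strain carried along with the floxed and null Pbx1 alleles in a mixed background are a candidate explanation, as is a response of these genes to Pbx1 loss, and the design does not separate them. The same count near Emx1, on chromosome 6, was 5 of 200, which 76.1% of windows did not reach, so variants carried with the Cre allele cannot be told apart from chance there. Emx1 itself was 1.54-fold lower, and whether the Cre insertion alters its transcript was not tested.

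By camera at the preset correlation the cell cycle list was lower and the neuronal maturation list higher. Neither was called with an estimated correlation (adjusted p = 0.667 for each) or by fry (adjusted p = 0.189 and 0.166), and a difference between the lists was not tested. Of 10000 random lists matched on mean signal, 0% lay below the cell cycle mean and 99.96% lay below the neuronal maturation mean. In the values used here this argues against a bias of the scaling with signal intensity. The random lists drew genes independently, so these shares ignore correlation among list members. They do not cover the choice of scaling, and the neuronal maturation call was lost with median scaling and with normexp. A later stage of the mutant embryos may lower dividing-cell genes and raise neuronal ones, but intermediate progenitor genes differed by -0.0265 (exact permutation p = 0.571), which settles nothing. The upper layer list, which a later stage would raise, shifted by -0.28 with an SE of 0.11. It lay more than 2 SE below 0, but its exact permutation p was 0.0857, and the exact test was taken as the rule after both were seen, so stage stays open there too. An effect of the genotype stays open and untested.

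Relabelling the 8 arrays bears on both counts. Of the 35 splits into 4 and 4 arrays, 2 gave at least 275 genes, so chance is not excluded over all splits. The other was the split by slide, with 3579 genes, which points to a structure of the arrays, and with the slide as a block 266 genes passed. Of the 8 splits that part all 4 same-numbered pairs, only the real one reached 275, and the highest of the others gave 5. With 8 splits the smallest share possible is 1 of 8, so this comparison cannot exclude chance either. For lists, 26 of the 35 splits called at least the 4 lists of the real split, and the highest of the other splits called 13, also among those parting all pairs. Chance is thus not excluded for the number of called lists.

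A scan of 156 gene families outside the fixed lists, formed by shared symbol stems with at least 10 measured members, showed the same dependence. Camera called 31 families at the preset correlation and 0 with an estimated one. For Ddx, Zbtb, Commd and Hspa, named after their values were seen, the estimates lay below the preset (0.00483, -0.0176, -0.0327 and -0.0349). Their calls were lost as well. The other called families had estimates above the preset, and the part of shared variation in their loss was not tested. Most of the 31 were lower, and the higher ones were Myh, Pcdhb, Gpr and Ankrd. Among the lower ones were Mrps (2 of 29 positive, mean -0.06), Psmd (0 of 14, mean -0.05) and Exosc (0 of 10, mean -0.08). These families were named after their values were seen. A shift to lower values was thus not particular to the cell cycle list. The mitochondrial ribosomal protein stem Mrpl led, with 1 of 49 Mrpl genes positive (mean -0.09, adjusted p = 1.79e-08, and 0.511 with an estimated correlation). Myh genes, named after their values were seen, shifted by a mean of 0.52 with 8 of 10 positive (adjusted p = 0.00237, and 0.511 with an estimated correlation).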
